A study of Homo sapiens with 4 samples.

How the data were processed

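RNA bound by A1CF, an RNA-binding protein known as a cofactor of apolipoprotein B mRNA editing, was measured by eCLIP (enhanced crosslinking and immunoprecipitation). In eCLIP, RNA is crosslinked by UV light to the proteins that touch it, partly digested, immunoprecipitated with an antibody to the protein, cut from a gel above the size of the protein, and sequenced beside a size-matched input from the same lysate that was not immunoprecipitated. Per the labels, frozen human tissue, named as brain, was ground and crosslinked 2 times at 254 nm with 400 mJ per square cm, and 50 mg of tissue went into each experiment. Per the labels, the gel window ran 75 kDa above the protein, which leaves about 150 nt of RNA, and one adapter carried a random sequence of 10 bases. There were 4 libraries, 2 immunoprecipitated and 2 inputs, numbered as replicates 1 and 2 by the labels. The labels do not say whether the replicates came from separate donors. Every p-value computed here has peaks or clusters of these lists as its units, and does not describe a population of samples.

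The deposited files were 3 peak lists, 1 for each immunoprecipitated library and 1 for both together. The submitters' processing notes name the genome build hg19 and the tools cutadapt, STAR, GATK, Picard and SAMtools, with no versions. The peak caller, the step that split peaks into abutting pieces, the test behind the p-values and the settings of the merging are not given in the sources used here. In each list the authors give every peak a log2 fold of the immunoprecipitated over the input library, and a −log10 p deposited beside it, with a ceiling of 400. Peaks were called on each library separately, and the name of the third list says that the replicates were compared by IDR (irreproducible discovery rate) and merged. All of these peak values are the authors' own. Here they served to rank, filter and describe peaks. Peaks on the Y chromosome were left out.

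Reads behind the folds are not listed, and were inferred. In each list the log2 folds were taken to equal the log2 of a ratio of whole numbers plus a constant. The constant stands for the log2 ratio of input to immunoprecipitated library size. It was set by assuming that the commonest fold of the list came from a fixed small number of immunoprecipitated reads over an input of 1. All inferred reads and library totals rest on that assumption. For each peak with a −log10 p above 0 and below the ceiling, pairs of whole read numbers that gave the fold were searched. A pair also had to give the deposited −log10 p within 0.1%. The p was computed by a two-sided exact binomial test, standing in for Fisher's exact test, or by a chi-square test with Yates' correction. Both took the ratio of library sizes as fixed. A pair was found for 72416 of 72810 such peaks in replicate 1 (99.5%) and 80490 of 81014 in replicate 2 (99.4%). With the p-values shuffled among 5000 peaks, 12.5% and 14.7% found a pair. The search tried only input numbers of 1 or more, so it cannot show how an input of 0 was counted. It was assumed here that an input of 0 was counted as 1. Library totals were then derived from the small part of large chi-square values that depends on them, over 677 and 552 peaks.

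The merged list gives 1 fold per peak. Every peak in it has the coordinates of a peak in the list of replicate 1 (2040 peaks) or of replicate 2 (1584), and 7 peaks in both lists are counted in each number. For those 7 the merged fold equals the mean of the 2 log2 folds, and the merged −log10 p was never above that of the peak's own list in any of the 3617. The fold of the other replicate over the same coordinates was therefore derived as 2 times the merged value less the listed one. The derived folds lay on the steps of the replicate they should belong to in 99.7% of cases for replicate 2 and 99.9% for replicate 1, and on the steps of replicate 1 in 61.1% of cases for those that should belong to replicate 2.

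An enriched peak had a log2 fold of at least 3 (8-fold) and a −log10 p of at least 3. Shares of peaks have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Overlaps were computed with bedtools 2.31.1, with at least 1 nt on the same strand, and tested with a two-sided Fisher's exact test in which the unit is the peak. Correlations of log2 folds used pairs of peaks that overlap by at least 50% of both lengths. The merged list is called the reproducible peaks. These choices, a first set of alternatives to them and the rule for named regions were fixed before the data were examined; further alternatives were added afterwards and are named as such where their values are given. The rule took the 15 regions with the highest merged fold, since no gene annotation of hg19 was used. It left out a stretch of chromosome X set to cover the gene XIST.

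Clusters were defined after the values were seen. A cluster joins listed peaks of both replicates on the same strand with gaps of at most 10 kb, and gives a rough stand-in for a transcribed region. Compact clusters spanned at most 25 kb and long ones over 100 kb, both with at least 10 listed peaks. Chromosomes were compared by a two-sided Fisher's exact test of clusters with and without a reproducible peak, 1 chromosome against all others, adjusted by Benjamini-Hochberg over 23 chromosomes. Odds ratios within classes of listed peaks or reads used the Mantel-Haenszel method. Peaks were also compared within classes of a single number of reads, joined from 200 up. Intervals for peaks within clusters came from 1000 resamples of whole clusters.

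The steps were tested on simulated data. Of simulated peaks with known reads, 99.9% were recovered with the true pair in replicate 1 (2437 peaks) and 99.9% in replicate 2 (2801 peaks). The simulated p-values came from the same formulas as the search, with inputs of at least 1. This checks the search only, and not whether the deposited values follow those formulas. With the enriched labels shuffled on the real coordinates, 0 of 20 overlap tests gave a p under 0.05. A planted odds ratio of 73.5 was recovered as 79.4 over 141295 peaks. For the stratified chromosome comparison, a planted odds ratio of 0.4 on chromosome 19 gave a median of 0.39 over 18001 clusters, and 19 of 20 intervals held the planted value. For positions within clusters, 18 of 20 intervals included 0 when labels were random, over 197284 peaks. A planted odds ratio of 2 between kinds of clusters was recovered as 2.12 over 12000 peaks.

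The planned tests of genic regions, gene lists, sequence motif and position in 3′ UTRs need an annotation or genome of hg19 and were not run. The gene lists and cell type markers fixed beforehand were not used for the same reason, and the labelled tissue was not checked against marker genes. The label names brain while the title concerns VLDL secretion, a process of the liver, so the tissue remains uncertain. Coordinates are hg19 and counted from 1, and none was converted to another build. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.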

Results

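The series is titled for the part A1CF plays in plasma triglyceride levels and the secretion of VLDL, the lipoprotein that carries triglycerides out of the liver. The data were eCLIP peaks of A1CF from tissue that the labels call brain, in 2 immunoprecipitated libraries, each set against its own size-matched input. From the folds and p-values, the immunoprecipitated library of replicate 1 was inferred to hold about 5000000 reads (interquartile range of the estimates 4970000 to 5040000) and its input 3210000. For replicate 2 the inferred totals were 3830000 (3800000 to 3840000) and 4220000. The title concerns a process of the liver and the labels name brain, so the tissue behind every peak below is uncertain. The list of replicate 1 held 141295 peaks and that of replicate 2 held 94077.

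The first question was where A1CF crosslinked to RNA above the input. In replicate 1, 5542 peaks were enriched at least 8-fold, which is 3.92% of the listed peaks (95% interval 3.82 to 4.02). In replicate 2, 4195 peaks were enriched, or 4.46% (4.33 to 4.59). The enriched peaks had a median log2 fold of 4.06 in replicate 1 and 4.005 in replicate 2, and the highest reached 9.21 and 8.53. They were wider than the other peaks, with medians of 51 against 30 nt in replicate 1 and 50 against 29 nt in replicate 2. They lay on both strands, 2855 plus and 2687 minus in replicate 1, and 2159 plus and 2036 minus in replicate 2. An enriched peak rested on a median of 45 immunoprecipitated and 2 input reads in replicate 1, and 28 and 2 in replicate 2. In 45.1% of enriched peaks with inferred reads in replicate 1 and 35.2% in replicate 2 the input number was 1, so the size of these folds is set by a single read or by none.

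The second question was whether the replicates found the same places. Of the 5542 enriched peaks of replicate 1, 3288 were overlapped by an enriched peak of replicate 2, which is 59.3% (58.0 to 60.6), against 0.989% of the other 135753 peaks (odds ratio 146, Fisher's exact test, −log10 p = 3956). In the other direction, 2842 of 4195 enriched peaks of replicate 2 were overlapped, or 67.7% (66.3 to 69.2), against 2.07% of the others (odds ratio 99.3, Fisher's exact test, −log10 p = 3032). Enriched labels spread at random over all listed peaks would give 182 and 210 overlapped peaks. That treats every listed peak as equally able to be enriched. Enriched peaks with inferred reads had at least 19 and 13 immunoprecipitated reads, while the medians of the others were 6 and 4. Depth was not matched, so the odds ratios do not separate shared depth from shared binding. Neighbouring peaks are often pieces of 1 site, so these p-values count some sites more than once. The share overlapped was higher at higher fold. It was 43.4% (41.5 to 45.4) for replicate 1 peaks with log2 folds of 3 to 4, and 64.0% (61.8 to 66.1), 88.7% (86.2 to 91.0) and 97.5% (95.1 to 98.9) in the bins of 4 to 5, 5 to 6, and 6 and above. For replicate 2 the share went from 56.7% (54.6 to 58.9) to 99.3% (96.37 to 99.98) over the same bins. Part of this rise is built in. The overlapping peak must itself pass the limits, and it fails them more readily when the fold lies just above 3.

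**Figure D1:**
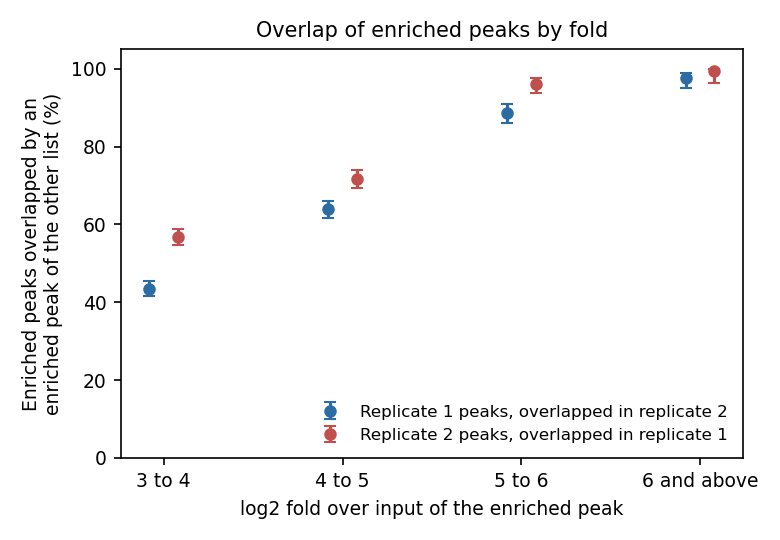
Share of enriched peaks of each replicate (y axis, percent) overlapped on the same strand by an enriched peak of the other replicate, by log2 fold over input (x axis). Points are shares and bars exact 95% binomial intervals; the lowest share is 43.4% and the highest 99.3%.

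Across 19865 pairs of peaks that overlap by at least 50% of both lengths, the log2 folds of the replicates had a Pearson r of 0.77 and a Spearman rho of 0.69. The correlation is across peaks, which are not independent replicates, and it includes peaks below input. Among the 17076 pairs above input in both replicates r was 0.68.

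The authors' merged list held 3617 reproducible peaks, 1842 on the plus and 1775 on the minus strand, with a median width of 51 nt. Their merged log2 fold had a median of 4.17 (interquartile range 3.67 to 4.78), and 177 of them reached 6 or more. The replicates' own folds averaged 4.43 in replicate 1 and 4.21 in replicate 2, and the SD between replicates, pooled over peaks, was 0.75 (n = 2). Across these peaks, which were selected on the mean of both folds, the folds of the replicates had a Pearson r of 0.50 and a Spearman rho of 0.41. Both folds were above input in all 3617 peaks. In 438 peaks (12.1%) 1 replicate lay under a log2 fold of 3, as low as 1.89, with the mean still at least 3. Of the reproducible peaks, 3 had a listed peak of either replicate on the opposite strand at the same place. Touching peaks joined into 2697 sites, of which 2188 were single peaks and the longest chain held 14.

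**Figure D2:**
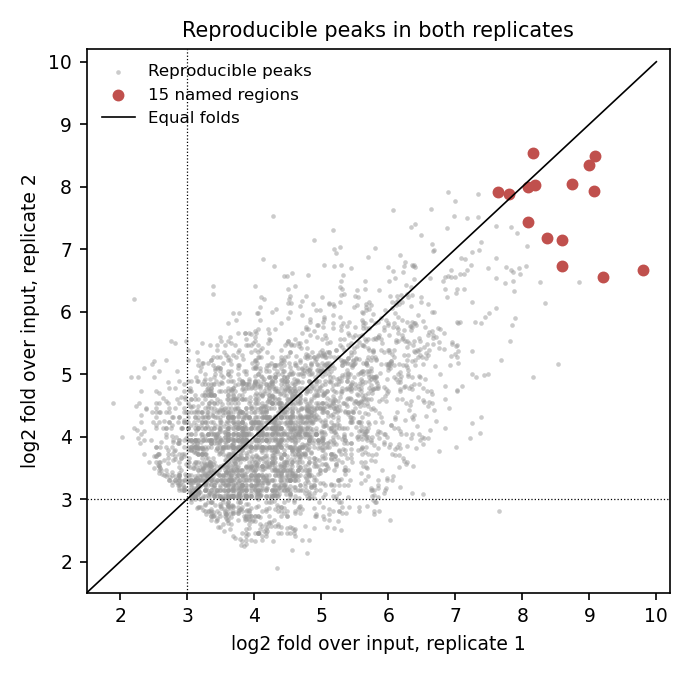
Log2 fold over input of the 3617 reproducible peaks in replicate 1 (x axis) and replicate 2 (y axis), 1 of them listed and the other derived from the merged value; red points are the 15 named regions, the diagonal marks equal folds and dotted lines mark a log2 fold of 3. The named regions reach 9.80 in replicate 1 and 8.53 in replicate 2.

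The 15 named regions, with the highest merged fold outside the stretch of chromosome X left out, fell into 7 sites, all on the plus strand. The strongest site, on chromosome 4 from 74321398 to 74321451, held 4 of them. Its highest piece, at 74321417 to 74321419, had log2 folds of 9.08 in replicate 1 and 8.49 in replicate 2 (mean 8.79 ± 0.42, SD, n = 2), and its lowest, at 74321445 to 74321451, had 8.09 and 7.43. A second site on chromosome 4, from 74286908 to 74286959, held 2 regions, the higher with folds of 9.07 and 7.94 (mean 8.50 ± 0.80). In these 6 regions on chromosome 4 the −log10 p stood at the ceiling of 400. No annotation was used to identify the 2 chromosome 4 sites. Their positions recall transcripts typical of liver, from general knowledge that was not checked here, which puts the labelled tissue in doubt. On chromosome 10, the site from 102124501 to 102124539 held 5 regions, and its highest piece, at 102124507 to 102124518, had closely similar folds of 8.18 and 8.03 (mean 8.11 ± 0.11). At its downstream edge, 102124535 to 102124539, the replicates stood further apart, at 8.60 and 6.73 (mean 7.67 ± 1.32).

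The other 4 sites were single regions. On chromosome 8, positions 22268314 to 22268355 had folds of 8.16 and 8.53 (mean 8.34 ± 0.27), and positions 17411822 to 17411856 had 7.63 and 7.91 (mean 7.77 ± 0.19). On chromosome 3, positions 41281648 to 41281654 had folds of 9.80, derived over the coordinates of the replicate 2 peak, and 6.66 (mean 8.23 ± 2.22), the widest gap between replicates among the 15. On chromosome 12, positions 69747967 to 69747972 had 9.21 and 6.55 (mean 7.88 ± 1.88). The order of these 2 among the 15 is within the spread between replicates. All 15 had a log2 fold of at least 6.55 in both replicates.

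Grouping the listed peaks by gaps of at most 10 kb, a step chosen after the values were seen, gave 18003 clusters, and 1244 of them (6.91%) held a reproducible peak. Reproducible peaks were concentrated. The 65 clusters with 10 or more held 1060 of the 3617 (29.3%), while 639 clusters held 1 each. The most were on chromosome 7, plus strand, from 94296815 to 94298938, where 65 reproducible peaks stood among 140 listed peaks within 2.12 kb. The median log2 fold of all listed peaks there was 4.40 and 128 of the 140 were enriched. The cluster on chromosome 12, plus strand, from 69747009 to 69747978 spanned 0.97 kb, and 75 of its 76 listed peaks were enriched, with a median of 5.43. On chromosome 6, the plus strand from 64268275 to 64292291 held 35 reproducible peaks among 84, and the minus strand from 119498616 to 119512057 held 31 among 82. The cluster on chromosome 10 that contains the named site ran from 102120944 to 102140533 with 33 among 110. In these 5 clusters 0 listed peaks lay below input. Listed peaks of both replicates are counted together here, while nearly every reproducible peak has the coordinates of a single list. The chromosome 12 cluster had 37 listed peaks in replicate 1, 39 in replicate 2 and 37 reproducible ones. The share of reproducible among listed peaks therefore understates how far the replicates shared these places.

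**Figure D3:**
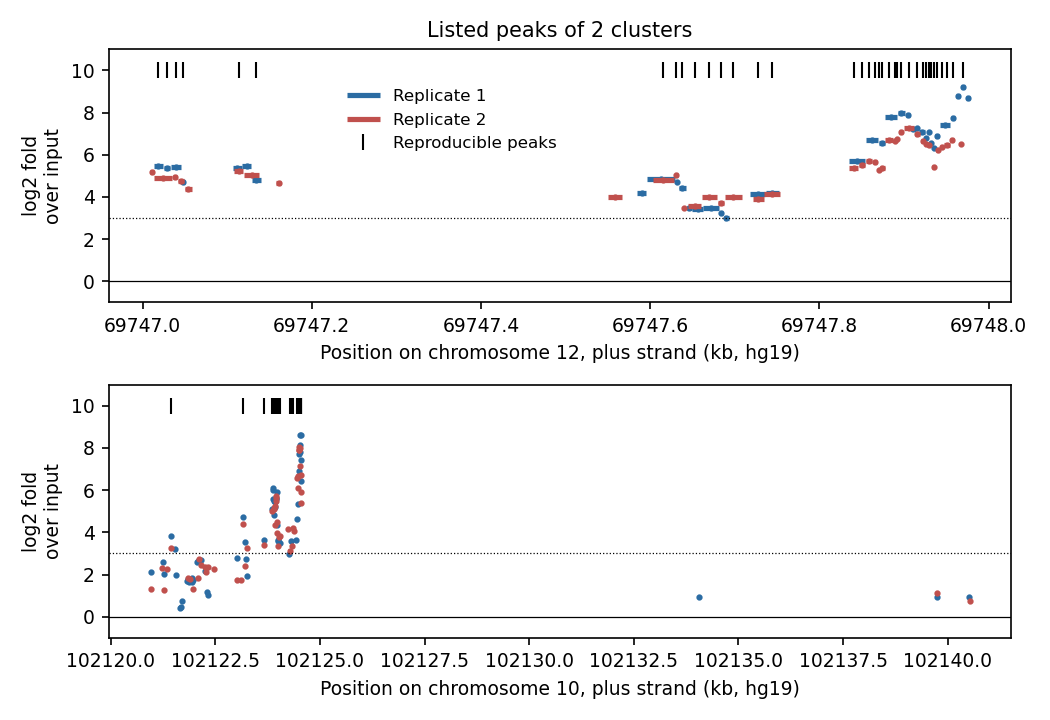
Listed peaks of replicate 1 (blue) and replicate 2 (red) in the clusters on chromosome 12 and chromosome 10, plus strand, with position in kb of hg19 (x axis) and log2 fold over input (y axis); black ticks mark reproducible peaks and the dotted line a log2 fold of 3. The chromosome 12 cluster holds 37 reproducible peaks and the chromosome 10 cluster 33. The highest merged folds lie toward the downstream end of the chromosome 12 cluster, but in the upstream part of the chromosome 10 cluster, at 102124501 to 102124539.

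Other regions had many listed peaks and few reproducible ones. The plus strand of chromosome 20 from 8113487 to 8571229 had the most listed peaks of any nuclear cluster, 1295, with a median log2 fold of 1.17 and 6 reproducible peaks. The minus strand of chromosome 3 from 65750625 to 66023950 had 652 listed peaks, a median of 0.95 and 0 reproducible peaks. For comparison, the median over all listed peaks was 0.95 in replicate 1 and 1.72 in replicate 2. Peaks with inferred reads that were not enriched had a median of 6 and 4 immunoprecipitated reads. The cluster medians therefore do not show weak binding spread over these regions. The minus strand of chromosome X from 132818553 to 133119550 had both, with 1114 listed and 27 reproducible peaks. On chromosome 2, minus strand, 216225239 to 216300774 held 24 reproducible peaks with a highest fold of 6.29, and 104 of its 209 listed peaks lay below input.

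Some RNA was lower in the immunoprecipitated libraries than in the input. In replicate 1, 21553 peaks (15.3%) lay below input, and in replicate 2, 8093 (8.60%). These shares use the sign of the fold alone, with no limit on p or reads. The log2 ratio of input to immunoprecipitated library size was −0.64 in replicate 1 and 0.14 in replicate 2. Equal reads thus count as below input in replicate 1 and above it in replicate 2, so the 2 shares are not directly comparable. A log2 fold of −3 or lower, a limit set after the values were seen, was found for 190 peaks in replicate 1 and 125 in replicate 2. At −2 the numbers were 584 and 333, and at −4 they were 112 and 36. Of the 190, 88 were overlapped by such a peak in replicate 2 (46.3%, 39.1 to 53.7), against 4 of the other 141105 (Fisher's exact test, p = 1.77e-257). The region furthest below input was on the minus strand of chromosome 3, at 181540742 to 181540766 in replicate 1 with a log2 fold of −9.73, overlapped in replicate 2 by 181540739 to 181540746 with −7.42. On the minus strand of chromosome 12, 6690712 to 6690727 had −6.75 in replicate 1 and the overlapping peak of replicate 2 had −5.33. On the plus strand of chromosome 15, 65597100 to 65597122 had −6.24 and its partner −5.63. On the plus strand of chromosome 11, 8706997 to 8707082 had −6.89 and its partner −4.86. Of the peaks at −3 or lower in either replicate, 0 overlapped a reproducible peak. The reproducible peaks all have a merged log2 fold of at least 3, which left little room for such an overlap.

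Most listed peaks of the mitochondrial plus strand lay below input. In replicate 1, 247 of its 273 peaks lay below input (90.5%, 86.4 to 93.7), with a median log2 fold of −0.998, and in replicate 2, 241 of 271 (88.9%, 84.6 to 92.4), with a median of −0.87. Over nuclear chromosomes 15.1% and 8.37% of peaks lay below input. Reads were not matched between mitochondrial and nuclear peaks, so how far depth sets this gap was not tested. On the mitochondrial minus strand, by contrast, 0 of 7 peaks in replicate 1 and 0 of 6 in replicate 2 lay below input, and their medians were 1.86 and 1.03. With so few peaks the 95% interval of the share below input still reaches 41.0% and 45.9%. The mitochondrial genome held 0 enriched peaks in either replicate on either strand.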

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

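The alternatives with log2 fold at least 1, log2 fold at least 4, −log10 p at least 5, overlap of at least 0.5 of the shorter peak or on either strand, other pairs for the correlation, overlapping enriched peaks as reproducible ones and left-out replicates were planned, except for clusters; those on peaks overlapped by any peak of the other list, input reads, folds in each replicate, joined sites, clusters, classes of reads and peaks far below input were chosen after seeing the data. A log2 fold of at least 4 lowered the enriched peaks to 2920 in replicate 1 and 2099 in replicate 2, the reproducible peaks to 2098 and the clusters with a reproducible peak to 804. A −log10 p of at least 5 left 2709 enriched peaks in replicate 2. Leaving out peaks with an inferred input of 1 left 3099 and 2750 enriched peaks, of which 131 and 94 have no inferred reads. Each of these limits removes peaks by its own construction. The mean number of enriched peaks, 4868.5, ranged from 4195 without replicate 1 to 5542 without replicate 2. Clusters with an enriched peak of a single replicate, a wider set than the 1244 with a reproducible peak, numbered 1477 without replicate 1 and 1757 without replicate 2. The share of enriched peaks overlapped between replicates stayed past the test's threshold under all 7 alternatives in each direction, from 52.4% to 67.3% for replicate 1, the latter among peaks overlapped by any peak of replicate 2, and from 56.7% to 77.5% for replicate 2; counting overlaps on either strand gave the same shares. The correlation was 0.89 over the 55 pairs with identical start and end, and 0.68 over pairs above input in both; the cause was not tested for the first, while the second leaves out the low end of the range. The peaks far below input rose from 190 to 584 in replicate 1 and from 125 to 333 in replicate 2 at a limit of −2, and numbered 112 and 36 at −4. Of the 70 alternatives over these results and those named under the other observations, 56 were the same, which means a count within 1.5 times the reported one, a tested value with the same direction and side of the threshold, or a correlation within the reported 95% interval; 13 moved, all named in this paragraph, and 1 lost its side of the threshold, the position within clusters of replicate 1 with a class for each number of reads (0.025). The 56 overstate how stable the results are. They include the 4195 and 5542 enriched peaks with a replicate left out, which are the reported counts themselves. They also include the clusters with a replicate left out, which count the wider set given above. A log2 fold of at least 1 could not be run for reproducible peaks, because the merged list starts at 3. The alternatives for genic regions, gene lists, motif and 3′ UTR position were not run without an hg19 annotation or genome. Leaving out a replicate gives no value for the overlap, the correlation or the merged list, which need both. No paired analysis was possible because no test here compares immunoprecipitated with input libraries: each fold is already the difference within a pair, and the folds were only counted, ranked and set beside each other. Depth limits the folds where the input number is 1, and limits peaks with few reads.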

Other observations

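The tests in this part were chosen after the peak values were seen, and those with a class for each number of reads, the unmatched differences over matched clusters and the intervals from resampled clusters after the first results of the same tests. The outcome expected under each explanation was written down before the stratified tests were run. No biological explanation was tested against another group, since the design has a single kind of tissue.

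Within clusters of at least 10 listed peaks, reproducible peaks lay toward the downstream end, read in the direction of the strand. On a scale from 0 at the upstream to 1 at the downstream end, reproducible peaks of 1086 clusters had a mean position of 0.73 and the other listed peaks 0.54. The difference was 0.19 (95% interval 0.17 to 0.20), positive in 819 clusters and negative in 267. It was 0.15 in compact clusters, 0.25 in those of 25 to 100 kb and 0.16 in long ones, and ranged from 0.13 to 0.22 over other gaps and single replicates.

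Reads per peak were weighed as an explanation of these positions. Matching by 7 classes of reads could be done in 565 clusters of replicate 1 and 548 of replicate 2. Over these clusters, with the same weights, the difference was 0.14 (0.11 to 0.16) and 0.18 (0.15 to 0.20) before matching and 0.024 (0.0051 to 0.042) and 0.074 (0.053 to 0.094) after it. Over peaks with at least 20 reads it was 0.029 (0.014 to 0.044) and 0.073 (0.054 to 0.093) with no matching, in 830 and 479 clusters. The 4 classes these peaks fill could be matched in 544 and 355 clusters. There, with the same weights, it was 0.042 (0.023 to 0.061) and 0.081 (0.056 to 0.106) before matching. After matching it was 0.021 (0.0011 to 0.040) and 0.064 (0.041 to 0.090). A class for each number of reads left only 131 and 119 clusters. There it was 0.048 (0.011 to 0.086) and 0.072 (0.029 to 0.117) before matching. After matching it was 0.025 (−0.023 to 0.070) and 0.060 (0.0056 to 0.108). With no minimum of reads, most of the difference in the matched clusters thus goes with reads. In replicate 2 the reads of a peak in its own replicate do not account for the whole. In replicate 1 the interval lies narrowly above 0 within classes of reads. With a class for each number of reads it includes 0, while the unmatched interval over the same clusters does not. Reads of the other replicate, on which a reproducible peak also depends, were not matched. The reads include the immunoprecipitated ones, so matching also removes part of any difference in binding; that A1CF binding may favour the downstream part of a transcribed region stays an open hypothesis, since the overall difference of 0.19 is the pattern itself and no test of it.

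Per listed peak, reproducible peaks were commoner in compact clusters, at 4.38% of 44694 peaks against 0.609% of 58462 in long ones. Both numbers of listed peaks count the lists of the 2 replicates together. Per cluster the share did not follow span. A reproducible peak was present in 38.8% (33.1 to 44.7) of the 286 long clusters, with a median of 158 listed peaks, in 17.9% (16.3 to 19.6) of the 2129 of 25 to 100 kb, with a median of 33, and in 25.1% (23.4 to 26.9) of the 2375 compact ones, with a median of 15. Among peaks with inferred reads, the odds ratio of compact against long clusters was 7.31 (5.63 to 9.71) in replicate 1 and 7.48 (5.82 to 9.82) in replicate 2.

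Peaks in compact clusters may rest on more reads, with medians of 11 against 8 in replicate 1 and 7 against 6 in replicate 2. Within classes of reads the odds ratio was 1.502 (0.96 to 2.25) in replicate 1 and 3.14 (2.33 to 4.17) in replicate 2, and 3.16 (2.35 to 4.23) in replicate 2 with a class for each number of reads. The share was higher in compact clusters in 6 of 7 classes of each replicate; in the class of 100 reads or more it was lower, at 69.0% against 84.1% in replicate 1 and 56.5% against 89.3% in replicate 2. The reads of a peak in its own replicate therefore do not account for the whole per-peak difference in replicate 2. Reads of the other replicate, on which a reproducible peak also depends, were not matched, so whether reads of both account for it stays open. In replicate 1 the question stays open, because the interval includes 1 and the classes rest partly on the immunoprecipitated reads that make a peak reproducible.

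The share of clusters with a reproducible peak differed from the rest on 2 of 23 chromosomes. It was 10.4% (8.84 to 12.1) of 1416 clusters on chromosome 2 (odds ratio 1.64, Fisher's exact test, adjusted p = 1.03e-05) and 2.51% (1.38 to 4.17) of 558 on chromosome 19 (odds ratio 0.34, adjusted p = 4.42e-05). Within 8 classes of listed peaks per cluster, the odds ratio of chromosome 2 was 1.10 (0.90 to 1.36), consistent with its clusters holding more peaks, and that of chromosome 19 was 0.53 (0.30 to 0.93). The last interval makes no allowance for 23 chromosomes: 5 of the 23 stratified intervals excluded 1, those of chromosomes 16 (0.56, 0.37 to 0.84), 17 (0.64, 0.46 to 0.91) and 19 below it and those of 4 and X above it. No chromosome passed after Benjamini-Hochberg adjustment of the stratified test, whose adjusted value was 0.149 for chromosome 19 and 0.094 for chromosome 16. Whether the low share of chromosome 19 goes beyond its number of listed peaks therefore stays open, and base composition and gene density were not tested.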
